A study of Mus musculus with 4 samples.

How the data were processed

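RNA was taken from flow-sorted MDSCs of EL4-bearing WT and Sphk2 KO mice, 2 libraries of each genotype, with genotypes and replicate numbers as the labels give them. Per the labels' protocols, libraries were built from 250 ng of total RNA (RINe 9.7 to 10) by poly(A) selection and a directional kit and sequenced as paired ends on a NovaSeq. The deposited table holds raw counts per Ensembl gene ID, with a column per library. Trim Galore, STAR, featureCounts and DESeq2 are named in the submitters' processing notes, with the genome build GRCm39. Their versions, the annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart, and reads of near-identical copies can be split or dropped, so such genes are named as uncertain.

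The table has 55416 gene IDs, of which 52083 (94.0%) have a symbol in the name table used and 3333 do not. Where several IDs share a symbol, the ID with the most counts kept it. The IDs without a symbol held 0.49% to 1.11% of the counts of a library, and 0 rows named no gene. The libraries held 16535999 and 14087613 counts in WT replicates 1 and 2 and 14386636 and 24685576 counts in Sphk2 KO replicates 1 and 2. The 10 most abundant genes took 8.79%, 9.55%, 9.72% and 10.65% of them, in that order, and mitochondrial genes 1.28% to 1.68%. No pair of libraries had identical counts, and the counts of replicates differed by more than sampling noise (chi-square over degrees of freedom 29.5 within WT and 19.1 within Sphk2 KO). Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.980 within WT, 0.984 within Sphk2 KO and 0.960 to 0.982 between genotypes. On the first principal component (60.8% of the variance), WT replicate 1 lay at -49.7, WT replicate 2 at -7.0, Sphk2 KO replicate 1 at 8.8 and Sphk2 KO replicate 2 at 47.9. On the second (25% of the variance), WT replicates 1 and 2 lay at 7.5 and -33.7. Sphk2 KO replicates 1 and 2 lay there at 28.5 and -2.4. On both components replicate 2 differed from replicate 1 in the same direction in each genotype. The labels do not say whether equal replicate numbers mark a shared batch.

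Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr and TMM with default settings, glmQLFit and glmQLFTest, genotype as the only term). All 4 libraries entered the fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of F, and its median over all tested genes was 0.28. Where a genotype had 3 counts or fewer in total, the ratio of pooled counts is given with an exact 95% binomial interval, or, at 0 counts, a lower bound against a floor of 3 counts over the group. Intervals and floors cover counting error only. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2.

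The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Sphk2 and Sphk1, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM, separate groups and a symbol that is not a predicted-gene or RIKEN name, up to 3 called members (2 for other cell types) and the most abundant uncalled member of each list, and a fixed set of lipid, MDSC, antigen presentation and sex-linked genes. It gave 4 genes higher and 7 lower. Other members that are named because they passed over their list alone were chosen after their values were seen. Single values of some genes that the rule or the lists select are not reported here. The 36 lists were tested with camera of limma 3.58.1 on the edgeR fit at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry, which asks whether the genes of a list move on balance in one direction without comparing them with other genes, were alternatives. Of the list members, Csta3, Hbb-b1, Hbb-b2 and Ahsp had no match among the symbols.

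The reference at hand was the GENCODE M21 annotation of GRCm38, not the build of the counts. It was used through gene IDs for chromosomes, gene order, overlaps and the test of called genes within 10 Mb of Sphk2 (Fisher's exact test, two-sided, 16353 tested genes with a position), and no coordinates are given. The share of the 75-base sequences of each called gene's longest transcript that occur in other genes' transcripts was counted in the same annotation. Genes that hold any of these sequences were taken as its copies.

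Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, library size alone, no count filter, a stricter filter (at least 1 CPM in 2 libraries and 100 counts in total), robust empirical Bayes, a block for the replicate number, glmTreat against a 1.2-fold change, windows of 5 and 20 Mb, and each library left out in turn. In the last, the genotype with a single library is assumed to vary like the other. Libraries thinned to equal totals, lists without chromosome 7 genes, a window of 100 genes in order and the count of calls on chromosome 7 under each setting were added after seeing the data. The steps were tested on simulated counts of the 16566 genes with 2 libraries against 2. The simulation changed 200 genes above a minimum mean count, a planted list and planted neighbors of Sphk2. Of the 200, 43.3% of 2-fold, 94% of 4-fold and 100% of 8-fold changes were recovered, and 3.3% of the calls were unchanged genes. With no gene changed there were 0 calls and 0 called lists. Genes were drawn independently of each other, so the 0 called lists say nothing of lists whose genes vary together. Each gene was drawn at the trended dispersion of genes of its abundance, with no spread of its own. Recovery in the real libraries can therefore be lower for genes that vary more than this trend.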

Results

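Poly(A) RNA was sequenced from myeloid-derived suppressor cells (MDSCs), the immature neutrophil-like and monocyte-like cells that accumulate in tumor-bearing hosts and restrain T cells. The cells were sorted by flow cytometry from the ascitic fluid of mice 14 days after they received EL4 cells, a mouse T cell lymphoma line. The mice were wild type (WT, 2 libraries) or lacked Sphk2 (Sphk2 KO, 2 libraries), the gene for sphingosine kinase 2, which phosphorylates sphingosine to sphingosine 1-phosphate. The comparison between them asks which transcriptional programs depend on sphingosine kinase 2 in these cells, among them immune suppression, lipid metabolism and inflammation. The libraries held 16535999 and 14087613 counts in WT replicates 1 and 2, and 14386636 and 24685576 counts in Sphk2 KO replicates 1 and 2. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these samples. All 4 libraries carried the Y-linked Ddx3y at 99.9 to 127.5 counts-per-million (CPM), with 4, 2, 1 and 1 counts of the X-inactivation transcript Xist.

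Sphk2 itself (ENSMUSG00000057342, chromosome 7) was 12.7-fold lower in the Sphk2 KO libraries. Its level was 54.3 ± 0.821 CPM in WT and 4.26 ± 0.270 CPM in Sphk2 KO (mean ± SD, n = 2 each), and its log2 fold change was -3.67 with a standard error of 0.186 (edgeR adjusted p = 0.000127). The Sphk2 KO libraries still held 57 and 100 Sphk2 counts, against 1033 and 743 in WT, and Sphk2 overlaps Dbp and Rpl18 on the opposite strand. Sphk1, the gene for the other sphingosine kinase, was near the floor, with 12 and 3 counts in WT and 7 and 24 in Sphk2 KO, and its log2 fold change of 0.86 (SE 0.625) did not pass the test (edgeR adjusted p = 0.642).

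Beyond Sphk2 the calls of edgeR at its default settings were few, and their number depended on the setting. Of 16566 genes tested, 7 rose and 11 fell in the Sphk2 KO libraries (edgeR, adjusted p under 0.05), and all 18 changed by at least 2-fold. At an unadjusted p under 0.05 there were 507 genes with higher and 1237 with lower values in Sphk2 KO. DESeq2 called 76 genes, edgeR without the count filter 615, and leaving out a library gave 54 (without WT replicate 1), 1061 (without WT replicate 2), 639 (without Sphk2 KO replicate 1) and 59 (without Sphk2 KO replicate 2). All 18 genes were among the calls in each of these.

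The deepest falls among the named genes were in tripartite motif genes, a family with antiviral members that forms a cluster on chromosome 7. Trim30d dropped from 283.8 ± 66.2 CPM in WT to 1.79 ± 0.419 CPM in Sphk2 KO (log2 fold change -7.27, SE 0.283). Trim12a had 2517 and 2884 counts in WT and 3 and 0 counts in Sphk2 KO, a pooled ratio of 2010 with a counting interval of 688 to 9750. Trim5 dropped from 22 ± 4.33 to 1.00 ± 0.408 CPM (log2 fold change -4.39, SE 0.335). Trim34b of the same cluster went the other way, from 2.54 ± 0.290 to 43.8 ± 6.22 CPM (log2 fold change 4.11, SE 0.227). The edgeR adjusted p of these 4 genes lay between 3.17e-05 and 0.00144. Of the 75-base sequences of their longest annotated transcripts, 44.8% in Trim34b, 22% in Trim5, 6.5% in Trim30d and 1.3% in Trim12a also occur in other genes, so the values of Trim34b, Trim5 and Trim30d are uncertain. Trim5 also shares 178 such sequences with other transcripts of Trim12a, which leaves the value of Trim12a uncertain too. Trim12a overlaps Gm15133 on the opposite strand, and Trim30d overlaps Gm16464 on the same strand.

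Other genes of chromosome 7 changed in both directions. Fut2, a fucosyltransferase that builds H antigen, rose from 24.4 ± 9.61 CPM in WT to 226.9 ± 11.5 CPM in Sphk2 KO (log2 fold change 3.22, SE 0.265, edgeR adjusted p = 0.00232). The zinc finger gene Zfp619 fell from 17.4 ± 0.694 to 3.25 ± 0.0577 CPM (log2 fold change -2.42, SE 0.235). Pak1, a kinase activated by Rac and Cdc42, rose from 19.2 ± 1.04 to 45.8 ± 0.0327 CPM (log2 fold change 1.25, SE 0.161, edgeR adjusted p = 0.0422), a call that was lost with limma-voom (adjusted p = 0.0539), with library size alone as the scaling (0.194), under a stricter count filter (0.0529) and with glmTreat (0.0714). On chromosome 9, Cadm1, a cell adhesion gene, rose from 1.59 ± 0.516 to 14.2 ± 0.508 CPM (log2 fold change 3.18, SE 0.311). Its neighbors Nxpe4 and Nxpe1-ps fell, Nxpe4 from 33.1 ± 4.92 to 3.31 ± 0.465 CPM and Nxpe1-ps from 11.6 ± 1.42 to 2.53 ± 0.0545 CPM. The call of Nxpe1-ps was lost with library size alone (edgeR adjusted p = 0.0691) and under the stricter filter (0.0529). Cadm1 overlaps Gm47198 on its own strand and Gm47197 on the other, and Nxpe4 overlaps Nxpe2 on the opposite strand.

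**Figure D1:**
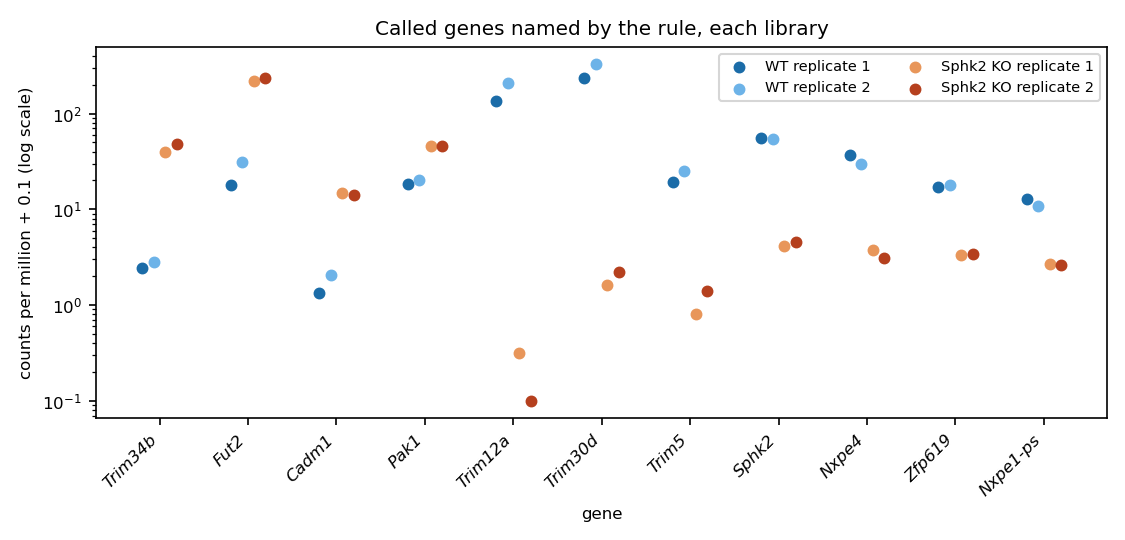
CPM plus 0.1 on a log axis for the 11 called genes that the naming rule selects, with 1 point for each of the 4 libraries (blue, WT; orange and red, Sphk2 KO). The naming rule admits only genes in which both Sphk2 KO points lie on the same side of both WT points, so this separation was set by the selection. Fut2, for example, had 24.4 CPM in WT and 226.9 CPM in Sphk2 KO on average.

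The remaining 7 called genes, chosen after their values were seen, also lie on chromosome 7 and are mostly predicted genes and pseudogenes. The pseudogene 9130208D14Rik had 3 counts over the WT libraries and 3355 over the Sphk2 KO libraries, a ratio of 1000 with a counting interval of 342 to 4860. The noncoding Gm35082 had 2 and 838 counts, a ratio of 375 with an interval of 104 to 3100. Klk1b22, a kallikrein-related gene, had 0 counts in WT and 111 in Sphk2 KO, at least 33.1-fold higher against a floor of 3 counts over the group. The call of Klk1b22 was lost under the stricter count filter (edgeR adjusted p = 0.0529). Gm16464 had 574 counts in WT and 0 in Sphk2 KO, at least 214-fold lower against the same floor. Gm1966, Gvin1 and Gm32633 fell, with log2 fold changes of -3.73, -5.08 and -2.47. The sequences of Gvin1 (98.3% shared with other genes), Gm16464 (74.2%), 9130208D14Rik (38.4%), Gm35082 (12%) and Gm1966 (5.6%) leave the assignment of their reads uncertain.

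By chromosome, as placed in the GRCm38 annotation, 15 of the 18 called genes lie on chromosome 7 and 3 on chromosome 9. Chromosome 7 holds 7.56% of the tested genes and 83.3% of the calls. No gene elsewhere or without a position was called by edgeR at its default settings, although 1485 of these 14404 genes had an unadjusted p under 0.05. Of such genes DESeq2 called 37 and edgeR without the count filter 511, and leaving out a library gave 21 (without WT replicate 1), 904 (without WT replicate 2), 546 (without Sphk2 KO replicate 1) and 27 (without Sphk2 KO replicate 2). Of the calls with a position, chromosome 7 then held 44.6% with DESeq2, 11.8% without the count filter, and 54.9%, 9.7%, 10.2% and 47.4% with the libraries left out, in that order. The region around Sphk2 was tested by itself: 4 of 143 genes within 10 Mb on either side were called, Sphk2 included, against 14 of 16210 genes elsewhere (odds ratio 33.2, 95% interval 7.87 to 108, Fisher's exact test, two-sided, p = 1.56e-05). Leaving Sphk2 out, the odds ratio was 24.9 (Fisher's exact test, p = 0.000399). The odds ratio was smaller with the calls of DESeq2 (8.27), without the count filter (1.89, Fisher's exact test, p = 0.0425), without WT replicate 1 (15.7), without WT replicate 2 (2.16), without Sphk2 KO replicate 1 (2.21) and without Sphk2 KO replicate 2 (11.2), and passed the test in each. In gene order, Fut2 lies 2 tested genes from Sphk2, Zfp619 lies 94 genes to one side and Pak1 258 genes to the other, and Trim5, the nearest called tripartite motif gene, 345 genes away.

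**Figure D2:**
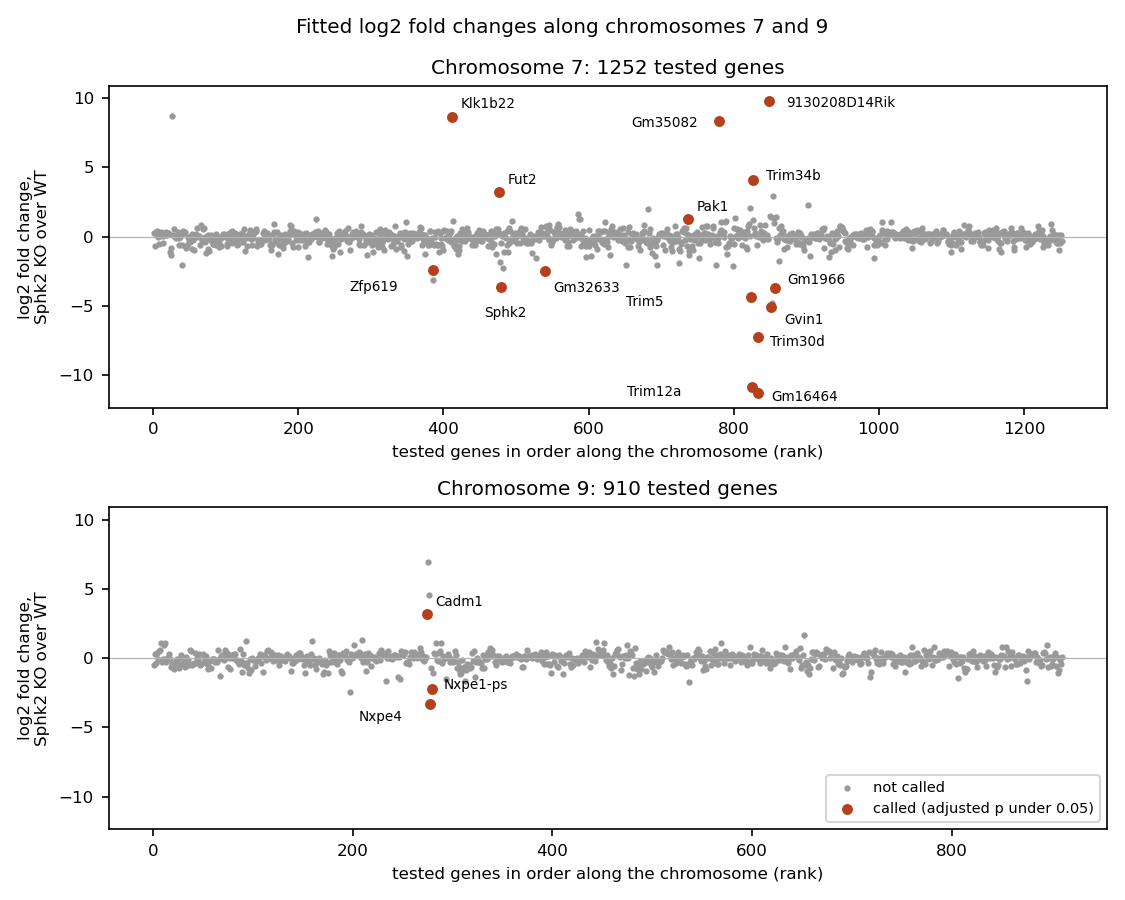
Fitted log2 fold change (Sphk2 KO over WT) of each tested gene against its rank along chromosome 7 (1252 genes) and chromosome 9 (910 genes), with called genes in red. Most called genes sit in a few stretches, on chromosome 7 around Sphk2 and around the tripartite motif cluster, with Pak1 and Gm35082 between them, and on chromosome 9 at Cadm1, Nxpe4 and Nxpe1-ps; the points of Klk1b22, Gm16464 and Trim12a, which have libraries at 0 counts, depend on the prior count of the fit.

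Gene groups were compared through 36 lists, with 686 tested members between them. No member of a list was called by edgeR over all genes, while 146 had an unadjusted p under 0.05 and DESeq2 called 17. As groups, 15 lists stood apart from the other genes with camera at a preset correlation of 0.01, 7 higher and 8 lower in Sphk2 KO. With an estimated correlation camera called 0 lists (1 list had an unadjusted p under 0.05). Fry, which tests a list against no change and not against other genes, also called 0 (3 lists had an unadjusted p under 0.05, smallest adjusted p = 0.47). Both Sphk2 KO libraries lay outside the WT range, on the same side, in 43.2% of all tested genes, against 33.3% by chance. Genes vary together, so with 4 libraries this share can lie away from 33.3% without an effect of genotype.

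In lipid metabolism, the list of fatty acid synthesis and desaturation was lower in Sphk2 KO as a group, with a median log2 fold change of -0.44 over 14 genes (camera adjusted p = 0.0272, and 0.62 with an estimated correlation). Of these genes, 9 had negative and 5 positive values. The median was -0.16 without WT replicate 1. Scd1, the stearoyl-CoA desaturase, was the only member past the threshold when adjusted over the list alone (log2 fold change -1.14, SE 0.238), and DESeq2 also called it over all genes. Fasn, the fatty acid synthase, had 39.0 ± 11 CPM in WT and 19.2 ± 7.59 CPM in Sphk2 KO (log2 fold change -1.03, SE 0.298, edgeR adjusted p = 0.402). Acaca, which encodes acetyl-CoA carboxylase 1, gave -0.53 (SE 0.303, edgeR adjusted p = 0.557), and Acly, the ATP citrate lyase, 0.03. Acacb was below the count filter, with 14 and 5 counts in WT and 3 and 5 in Sphk2 KO. Genes of cholesterol synthesis were slightly higher, with a median of 0.20 over 23 genes (camera adjusted p = 0.0209; adjusted p = 0.66 with an estimated correlation), 0 of them past the threshold adjusted over the list alone. That call was lost without WT replicate 2 (median 0.24, camera adjusted p = 0.152) and without Sphk2 KO replicate 1 (median 0.10, camera adjusted p = 0.457), and the median was 0.34 without Sphk2 KO replicate 2. Srebf2, the regulator of this pathway, gave 0.27 (SE 0.190).

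The sphingolipid genes did not stand apart, with a median of -0.03 over 36 genes (camera adjusted p = 0.788), and Cers6, a ceramide synthase and their most abundant member, gave 0.43 (SE 0.227). The list of phosphatidylcholine and glycerophospholipid synthesis had a median of -0.01 over 26 genes (camera adjusted p = 0.823). Within it, Pcyt1a, the rate-limiting enzyme of phosphatidylcholine synthesis from choline, had 108.4 ± 22 CPM in WT and 135.1 ± 6.80 CPM in Sphk2 KO (log2 fold change 0.32, SE 0.177, edgeR adjusted p = 0.548). Chka, a choline kinase, gave -0.06 (SE 0.160), and Slc44a2, a choline transporter-like gene, 0.18. For fatty acid uptake, storage and oxidation the median was 0.03 over 33 genes (camera adjusted p = 0.995), and Dgat1 gave 0.17. For the targets of LXR and cholesterol efflux it was -0.12 over 14 genes (camera adjusted p = 0.27), and Abca7 gave 0.14. Abca1, the cholesterol exporter, at -0.73 (SE 0.169), and Apoe at -0.54 (SE 0.151) passed when adjusted over that list alone. In the sphingolipid and phosphatidylcholine lists the median and mean were below 0 while camera ranked them upward, and in the list of fatty acid uptake the mean was -0.08 against a median above 0.

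Genes of MHC class II presentation were lower in Sphk2 KO, with a median log2 fold change of -0.75 over 15 genes (camera adjusted p = 1.64e-10; adjusted p = 0.62 with an estimated correlation). All 15 had both Sphk2 KO libraries below both WT libraries, and 10 passed when adjusted over the list alone. Cd74, the invariant chain, had 603.4 ± 30.6 CPM in WT and 359.1 ± 144.9 CPM in Sphk2 KO (log2 fold change -0.75, SE 0.282, edgeR adjusted p = 0.429). H2-Ab1 had 172.9 ± 12.5 and 103.8 ± 42.1 CPM (log2 fold change -0.74, SE 0.257, edgeR adjusted p = 0.425). The median was -1.23 without Sphk2 KO replicate 1 and -0.38 without Sphk2 KO replicate 2. The B cell list had a median of -0.67 in the same comparison. MHC class I genes did not stand apart (median 0.10 over 21 genes, camera adjusted p = 0.362), and H2-D1 gave 0.24 (SE 0.283). Costimulation and dendritic cell maturation gave a median of -0.09 over 14 genes (camera adjusted p = 0.521), with Cd80 at 0.08 (SE 0.171), Cd86 at -0.15 (SE 0.182), Cd40 at -0.54 (SE 0.303) and Marcksl1 at 0.03. Il12b had 0 counts in all 4 libraries.

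The list of myeloid suppressor genes had a median of 0.20 over 30 genes (camera adjusted p = 0.00873; adjusted p = 0.63 with an estimated correlation). Nos2, the inducible nitric oxide synthase, was its only member past the threshold adjusted over the list alone, at 14.2 ± 2.56 CPM in WT and 30.2 ± 4.16 CPM in Sphk2 KO (log2 fold change 1.09, SE 0.209), and it missed the threshold over all genes (edgeR adjusted p = 0.191) but not with DESeq2 (adjusted p = 0.013). Arg1, arginase 1, was barely expressed, with 1.56 ± 0.0353 CPM in WT and 1.00 ± 0.60 CPM in Sphk2 KO (log2 fold change -0.71, SE 0.50, edgeR adjusted p = 0.634). Cd274, which encodes PD-L1, gave 0.40 (SE 0.177, edgeR adjusted p = 0.473), and Lilrb4a 0.27 (SE 0.312). Without WT replicate 1 the median of the list was 0.03 and without Sphk2 KO replicate 2 it was 0.12, and the call was lost in both (camera adjusted p = 0.499 and 0.0708). It was 0.46 without WT replicate 2 and 0.32 without Sphk2 KO replicate 1. Genes of NADPH oxidase and reactive oxygen had a median of 0.13 over 18 genes (camera adjusted p = 0.711).

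Interferon-stimulated genes were higher in Sphk2 KO. The type I interferon list had a median of 0.62 over 34 genes (camera adjusted p = 4.98e-13; adjusted p = 0.62 with an estimated correlation), with 30 positive values. Cmpk2 alone passed when adjusted over that list (log2 fold change 0.98, SE 0.162), and Oasl2, its most abundant member, had 699.8 ± 312.7 CPM in WT and 981.3 ± 332.1 CPM in Sphk2 KO (log2 fold change 0.49, SE 0.361). The median was 0.31 without WT replicate 1 and 1.03 without WT replicate 2. The interferon gamma list had a median of 0.37 over 21 genes (camera adjusted p = 0.000481; adjusted p = 0.62 with an estimated correlation), 0.21 without WT replicate 1 and 0.62 without WT replicate 2. Adjusted over that list alone, the guanosine triphosphatase genes Igtp (1.01, SE 0.225), Irgm1 (0.82, SE 0.186) and Irgm2 were higher and Ciita, the activator of MHC class II genes, was lower. Irf1 had 260.0 ± 59.5 CPM in WT and 385.8 ± 20.5 CPM in Sphk2 KO (log2 fold change 0.57, SE 0.208, edgeR adjusted p = 0.425). NF-kB and inflammatory cytokine genes had a median of 0 and a mean of -0.07 over 30 genes (camera adjusted p = 0.755), and Il1b, at 4947 ± 1432 CPM in WT, gave 0.07 (SE 0.404). Their median was 0.33 without WT replicate 2 (camera adjusted p = 0.00268) and -0.24 without WT replicate 1 (camera adjusted p = 2.3e-06). Chemokines and their receptors had a median of 0.05 and a mean of -0.14 over 15 genes (camera adjusted p = 0.711), and Cxcr2 gave 0.36 (SE 0.351).

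Among markers of myeloid identity, both lists of later neutrophil stages were higher in Sphk2 KO and the monocyte list was lower. The mature neutrophil list had a median of 0.39 over 23 genes, all with positive values (camera adjusted p = 1.18e-09; adjusted p = 0.62 with an estimated correlation). Its median was 0.16 without WT replicate 1 and 0.83 without WT replicate 2. Ly6g, which encodes the granulocytic MDSC marker, had 58.2 ± 15.7 CPM in WT and 107.6 ± 7.16 CPM in Sphk2 KO (log2 fold change 0.89, SE 0.199, edgeR adjusted p = 0.302), and with Retnlg, Stfa2l1 and Fpr2 it passed when adjusted over the list alone. S100a9, the most abundant member, gave 0.74 (SE 0.465). Secondary and tertiary granule genes had a median of 0.39 over 18 genes (camera adjusted p = 9.32e-09; adjusted p = 0.62 with an estimated correlation), 0.25 without Sphk2 KO replicate 1 and 0.60 without Sphk2 KO replicate 2. Mmp8 (0.98, SE 0.209), Wfdc21 (0.95, SE 0.158) and Ly6g passed when adjusted over that list alone, while Ngp gave 0.35 (SE 0.346). The primary granule and precursor list had a median of -0.78 over 10 genes and did not stand apart (camera adjusted p = 0.14), and Igsf6 gave 0.32. It was called with chromosome 7 genes left out (median -0.96, camera adjusted p = 0.0356), without WT replicate 2 (median -1.43, camera adjusted p = 1.95e-07) and without Sphk2 KO replicate 1 (median -1.35, camera adjusted p = 1.08e-07). Monocyte genes had a median of -0.60 over 22 genes (camera adjusted p = 1.19e-05; adjusted p = 0.62 with an estimated correlation), 0 of them past the threshold adjusted over the list alone, and the median was -0.34 without WT replicate 1 and -0.30 without Sphk2 KO replicate 2. Ly6c2 gave -0.10 (SE 0.262) and Nr4a1 -0.17 (SE 0.20). The macrophage list had a median of -0.06 and a mean of -0.10 over 25 genes while camera ranked it upward (camera adjusted p = 0.995), and Ctsd, its most abundant member, gave 0.45 (SE 0.196).

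Markers of cells outside the sorted population also differed between the genotypes. The T cell and EL4 lymphoma list was lower in Sphk2 KO, with a median of -1.18 over 22 genes (camera adjusted p = 8.42e-12; adjusted p = 0.62 with an estimated correlation) and -0.77 without WT replicate 1. Of its members, 12 passed when adjusted over the list alone. They included Thy1 (-2.43, SE 0.441) and Tcf7, which had 20.1 ± 7.38 CPM in WT and 5.60 ± 1.06 CPM in Sphk2 KO (log2 fold change -1.86, SE 0.306, edgeR adjusted p = 0.138), and DESeq2 called both over all genes. The B and plasma cell list had a median of -0.67 over 18 genes (camera adjusted p = 3.37e-11; adjusted p = 0.62 with an estimated correlation), with 14 members below the threshold adjusted over the list alone, among them Ighd (-0.94, SE 0.201), and a median of -0.44 without Sphk2 KO replicate 2. Ighm, the most abundant member, gave -0.26 (SE 0.384). The dendritic cell list had a median of -0.56 over 15 genes (camera adjusted p = 0.0068; adjusted p = 0.62 with an estimated correlation), -1.08 without Sphk2 KO replicate 1 and -0.35 without Sphk2 KO replicate 2, where the call was lost, and Ly6d gave -0.72 (SE 0.283). The mesothelial and fibroblast list held 5 tested genes with a median of -3.3 (camera adjusted p = 1.28e-05; adjusted p = 0.62 with an estimated correlation). Col3a1 (-3.66, SE 0.655), Pdgfra and Col1a2 passed when adjusted over that list alone, all 3 at low counts, and C3 gave -0.06. Its median was -1.80 without WT replicate 2, -1.70 without Sphk2 KO replicate 1 and -1.90 without Sphk2 KO replicate 2.

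Erythroid genes were higher in Sphk2 KO, with a median of 1.47 over 14 genes (camera adjusted p = 6.81e-16; adjusted p = 0.62 with an estimated correlation) and 2.37 without WT replicate 2. Of the 14, 12 passed when adjusted over the list alone, including Slc4a1, the anion exchanger of the red cell membrane (2.19, SE 0.409). Hbb-bs, a beta-globin gene, had 61.7 ± 45.6 CPM in WT and 263.4 ± 125.4 CPM in Sphk2 KO (log2 fold change 2.10, SE 0.511, edgeR adjusted p = 0.349). It lies on chromosome 7 at rank 822 in gene order, close to the called Trim5 at rank 824. The beta-globin gene Hbb-bt beside it gave 0.90. The erythroid list was still called with chromosome 7 genes left out. Markers of NK cells (median -0.39, Txk -0.34), resident peritoneal macrophages (median 0.10, F5 0.17), eosinophils (median -0.15, Siglecf -0.11), mast cells and basophils (median 0.14, Kit 0.98) and platelets and megakaryocytes (median -0.01, mean 0.04, Itgb3 0.31) did not stand apart, with camera adjusted p between 0.132 and 0.823. The mast cell list was called without Sphk2 KO replicate 2 (median 0.46, camera adjusted p = 0.000256). Saa3 in the peritoneal macrophage list and Kit in the mast cell list were higher when adjusted over the list alone. Saa3 also lies on chromosome 7, at rank 494 in gene order, close to Sphk2 at rank 479.

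**Figure D3:**
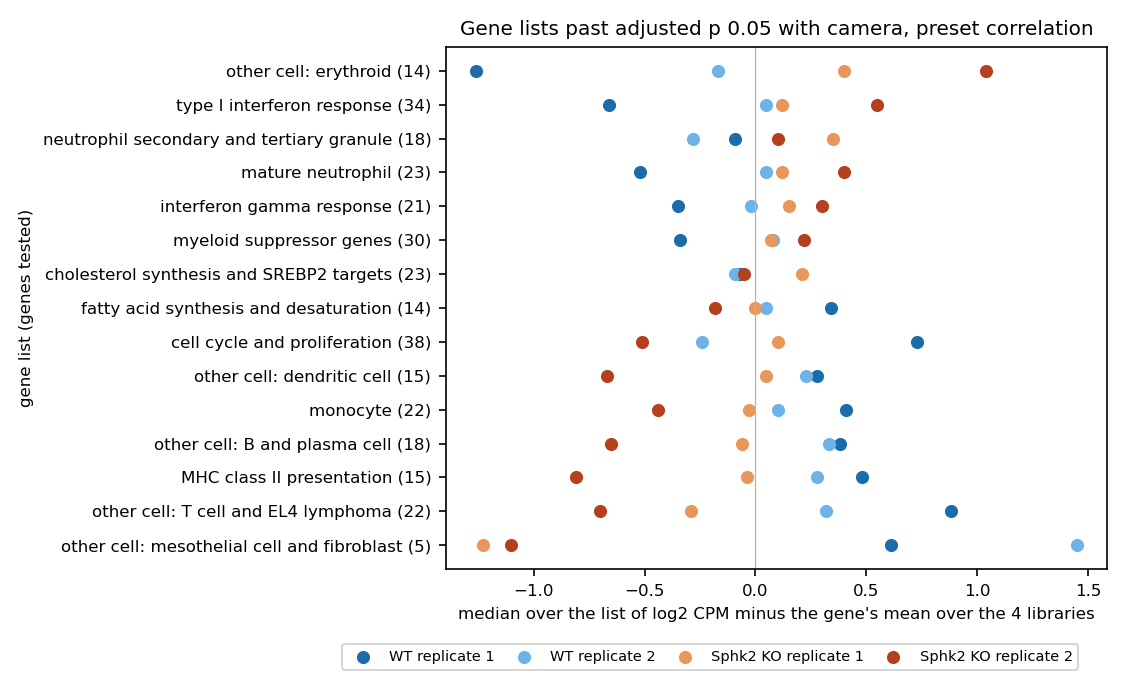
Median over each called list of the log2 CPM of its genes minus each gene's mean over the 4 libraries, with 1 point per library and the number of tested genes in parentheses. In most lists WT replicate 1 and Sphk2 KO replicate 2 lie at the ends and the other libraries between them, as in the type I interferon list at -0.66 and 0.55 against 0.05 and 0.12.

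Proliferation genes had a median of -0.47 over 38 genes (camera adjusted p = 0.000406; adjusted p = 0.83 with an estimated correlation), 0 of them past the threshold adjusted over the list alone, and Mki67 gave -0.12 (SE 0.252). Without WT replicate 1 the median was 0.05 (camera adjusted p = 0.513). It was -0.91 without WT replicate 2, -0.81 without Sphk2 KO replicate 1 and -0.23 without Sphk2 KO replicate 2, where the call was also lost (camera adjusted p = 0.121). The lists of glycolysis and hypoxia (median 0.14, Pkm 0.22), the mitochondrial respiratory chain (median -0.16, Atp5b -0.17) and the unfolded protein and integrated stress response (median -0.17, Hspa5 0.06) did not stand apart, with camera adjusted p of 0.0814, 0.352 and 0.061. The last list was called with library size alone (camera adjusted p = 0.0219), without the count filter (0.0278), under the stricter filter (0.0479), with chromosome 7 genes left out (0.0356), without WT replicate 2 (0.0224) and without Sphk2 KO replicate 1 (0.00571). Glycolysis and hypoxia was called without the count filter (camera adjusted p = 0.0235) and without WT replicate 2 (0.0456), and the respiratory chain without WT replicate 2 (0.030). Immediate early and heat shock genes, which respond to handling, had a median of 0.19 (camera adjusted p = 0.132) and were called without WT replicate 2 (median 0.48, camera adjusted p = 6.42e-05) and without Sphk2 KO replicate 1 (median 0.20, camera adjusted p = 0.000643), and sex-linked genes a median of 0.07 (camera adjusted p = 0.711).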

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

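The settings with thinned libraries, lists without chromosome 7 genes and a window in gene order were chosen after seeing the data. Sphk2 stayed called under every setting, between -3.61 and -3.84, and the odds ratio of calls near Sphk2 stayed above 1, from 1.58 with the replicate block (Fisher's exact test, p = 0.0287) and 1.89 without the count filter to 35.8 with glmTreat. The 18 genes called at the main settings, all with at least a 2-fold change, were 76 (73 with at least 2-fold) with DESeq2 and 615 (376) without the count filter. Leaving out a library gave 54 to 1061 (51 to 613), and the cause of these larger counts was not tested. With the replicate number as a block there were 2637 calls (579 with at least 2-fold), 2254 of them off chromosomes 7 and 9 or without a position and 8.9% on chromosome 7. The labels share only the numbers, over 2 pairs, and the correlation of replicate 1 minus replicate 2 between the genotypes was 0.44 across genes. The 18 genes remained called under DESeq2, RLE, no filter, robust empirical Bayes, the block, each left-out library and thinning (20 calls), and 17 of them with limma-voom, 16 with library size alone, 15 under the stricter filter and 17 with glmTreat. Library size alone shifted the median of all genes to -0.17 from 0, so its values are relative to that shift. The 15 called lists became 0 with an estimated correlation and 0 with fry; the estimated correlations of the called lists ran from 0.03 to 0.90, against the preset 0.01. Of the lists, cell cycle turned from a median of -0.47 to 0.049 without WT replicate 1 (range over left-out libraries -0.91 to 0.049), and NF-kB from 0 to 0.332 without WT replicate 2 (range -0.239 to 0.332); the cause was not tested. At this depth and n, the simulation recovered 43.3% of 2-fold changes in genes above a minimum mean count. Smaller changes, and changes of genes with fewer counts or with more spread than the simulated trend, can be missed. Slc4a1, with a log2 fold change of 2.19 (SE 0.409), was not called by edgeR over all genes (adjusted p = 0.191).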

Other observations

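DESeq2, camera and fry were planned, and the other tests in this part were chosen after the results they bear on were seen.

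DESeq2 called genes that edgeR at its default settings and limma-voom did not. Among its 37 calls off chromosomes 7 and 9 or without a position, 18 were higher and 19 lower in Sphk2 KO. Red cell genes recur among the higher ones: Slc4a1 (DESeq2 log2 fold change 2.21), Ank1 (1.85), Dmtn (2.65), Ermap (2.18), Kel (2.64) and Aqp1 (1.91). The serine synthesis genes Phgdh (DESeq2 log2 fold change -1.67) and Psat1 (-1.59) were lower, as were Bcat1 (-3.09), a branched-chain aminotransferase, and the mitochondrial chaperone Hspd1 (-1.06). The chemoattractant gene Prok2 (DESeq2 log2 fold change 1.04) was higher.

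Of the 17 called genes other than Sphk2, chromosome 7 held 82.4% (exact interval 56.6 to 96.2, Fisher's exact test p = 1.2e-13), which argues against effects of Sphk2 loss spread over the genome for these genes; beyond them such effects cannot be told apart from differences between libraries, because the calls off chromosomes 7 and 9 or without a position numbered 0 at the default settings and 904 without WT replicate 2, where chromosome 7 held 9.7%. The exact interval and Fisher's test of the 17 genes count them as independent. Several of them overlap or share sequence, so that interval is too narrow and that p too small. An effect of the edit on adjoining genes is argued against for the 10 called genes more than 100 tested genes from Sphk2, and linkage to Sphk2 is excluded for the 3 genes of chromosome 9. For 11 called genes the summed level of their copies could not supply the change between any pair of WT and Sphk2 KO libraries. Of these, 6 shared no sequence. Reads moved from copy to copy are argued against for these genes other than Trim12a, as far as the longest transcripts show. Trim12a stays open, because only the longest transcript of each gene was searched and Trim5 shares 178 sequences with its other transcripts. Trim5 was itself lower, but further genes that share sequence with those transcripts were not counted. For the other 6 (Trim30d, Trim5, Gm35082, Gm1966, Gvin1 and 9130208D14Rik) moved reads cannot be excluded, because differences of the copies between single libraries were large enough to supply the change. The mean of the copies moved the same way as the gene for Trim30d and 9130208D14Rik. It moved the other way for Gm35082, Gvin1 and Gm1966. For Gm1966 the copies rose from 485.4 CPM in WT to 1334 CPM in Sphk2 KO on average. Gm1966 itself fell from 638.3 to 47.9 CPM. For Trim5 the copies fell from 327.5 CPM in WT to 242.7 CPM in Sphk2 KO in sum. They include Trim12a, itself called and lower (171 to 0.107 CPM), so that fall does not speak against moved reads. Gm8995, a copy of the lower Gm1966 and Gvin1, had 473.6 ± 124.1 CPM in WT and 1229 ± 96.7 CPM in Sphk2 KO (edgeR adjusted p = 0.191). DNA of another strain carried along with the targeted allele is a candidate explanation, since uncalled genes of chromosome 7 that neither overlap a called gene nor share sequence with one had an unadjusted p under 0.01 in 4.0% of cases against 2.19% elsewhere (odds ratio 1.86, interval 1.34 to 2.54, Fisher's exact test p = 0.000162), though for 4 genes within 100 tested genes it cannot be told apart from an effect of the edit on its neighbors, and for the genes of chromosome 9 a second such region and an effect of genotype cannot be told apart, because the odds ratio of uncalled genes within 100 tested genes of them was 1.88 with an interval of 0.795 to 3.83.

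MHC class II genes were lower together with the B cell, dendritic cell (median -0.56) and monocyte (median -0.60) lists. The MHC class II median minus the B cell median was -0.08 (bootstrap interval -0.16 to 0.05), with a gap of at most 0.16 in any library, and minus the dendritic cell median -0.19 (interval -0.61 to 0.04), with a gap of at most 0.20. A smaller share of B cells or of dendritic cells, both of which a sort for MDSCs would remove, may therefore account for the lower values, although Ighm, the most abundant B cell gene, differed less (661.9 ± 118.0 CPM in WT, 551.3 ± 329.8 CPM in Sphk2 KO) and Ly6d, the most abundant dendritic cell gene, had 22.9 ± 3.09 CPM in WT and 14.0 ± 5.55 CPM in Sphk2 KO. The macrophage median lay 0.61 above the B cell median (interval 0.45 to 0.89), so these lists did not fall alike in these libraries. The bootstrap intervals resample the genes of each list and do not measure the spread between libraries. A uniform loss of every cell type but neutrophils is therefore not decided by them, also because sorted myeloid cells may express macrophage list genes themselves. A lower MHC class II level within the myeloid cells themselves cannot be told apart, because the B cell interval reaches 0.05 and bulk libraries do not separate the cells. Nor can a smaller share of monocytes, because the gap reached 0.37 in 1 library. Without members shared with the MHC class II list, the difference from the monocyte median was -0.13 (interval -0.52 to 0.07).

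The type I interferon list was higher in Sphk2 KO. The median was 0.60 after thinning to equal totals. The values were already scaled by library size and thinning leaves expected ratios unchanged. Thinning therefore cannot tell whether depth, or a difference that goes with it, contributed. Differences between single libraries could account for it: Sphk2 KO replicate 1 lay 0.07 above WT replicate 2, while the libraries differed by 0.71 within WT and by 0.43 within Sphk2 KO. An effect of genotype on interferon signaling stays open: the list stood apart from other genes with camera at the preset correlation (adjusted p = 4.98e-13) but not with an estimated correlation (adjusted p = 0.62), fry, which tests it against no change, gave an adjusted p of 0.48, and a p that misses the threshold does not exclude an effect.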
